A study of Streptococcus oralis with 11 samples.

How the data were processed

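RNA was measured by sequencing in Streptococcus oralis ATCC 9811. Per the labels' protocols, cells were precultured for 18 h at 37 °C without oxygen, and a bioreactor with brain heart infusion medium, 5% sucrose and vitamin K was inoculated to a density (OD600) of 0.026. Medium from it passed at 100 µl/min through flow chambers that held a titanium or a SLIPS surface. Biofilm was taken from the chambers and planktonic cells from the bioreactor. The labels put 4 libraries in the titanium group, 4 in the SLIPS group and 3 in the planktonic group, and they name polyA RNA as the molecule, with no statement of how ribosomal RNA was removed.

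The authors deposited 3 tables of normalized counts, one for each pair of groups, a signal in which the reads of a gene are divided by a size factor of the library. Trim Galore 0.4.3.1, FastQC 0.69, HISAT2 2.1.0, HTSeq 0.9.1 and DESeq2 2.11.40.1 are named, per the submitters' processing notes, without their roles or settings. The genome build and the strand setting of the counting are not given in the sources used here. The files list 1810 features (1794 protein-coding genes and 16 tRNA genes) on 3 contigs, with an ID, a start, an end and a function text each; no ribosomal RNA gene is among them. Gene names, functions and positions were used as the files give them, and no reference genome was used. IDs are printed without the prefix that all of them share in the files (the word fig and the number of the genome), so that peg and rna start the IDs of protein-coding and RNA genes. A function text is shared with another feature for 571 features, so reads split between near-identical copies could not be judged, and neighbouring genes that overlap by a few bases may share reads.

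Within a library every value was a whole multiple of one step, and dividing by that step gave whole numbers for 100% of the values (tolerance 0.01). These recovered reads came to 10.9 to 17.5 M per library and 143 M in all. The step of a library differed between tables, so each table was normalized on its own, and all tests were made within a table. The search for the step was tested on simulated data, where it found all reads in 22 of 22 columns. Depth at this level left 8 to 13 features at 0 per library, and reads of replicates differed far beyond counting error (chi-square per degree of freedom 97.2 to 1273), which says nothing on whether the libraries are independent.

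For each pair of groups, genes with a mean of 10 or more normalized counts over the libraries of the table were tested with limma 3.58.1 (R 4.3.3) on log2(normalized count + 1), with an intensity trend, without covariates, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in the comparison, and genes were called at an adjusted p under 0.05. Fold changes carry limma's standard errors and 95% intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading the tables and drawing. The script was tested on simulated data with independent noise per gene, 10 sets of 200 changed genes per comparison. At a true change of 4-fold in the simulated genes it recovered 80.0% of the changed genes for titanium against planktonic cells (1793 genes), 73.4% for SLIPS against planktonic cells (1792 genes) and 83.7% for SLIPS against titanium (1795 genes), and at 2-fold 37.0%, 30.8% and 44.8%. False calls made up 5.03%, 5.85% and 5.08% of calls. A planted list of 20 genes changed 2-fold was found in 10 of 10 sets in each comparison, and an unchanged list in 0, 0 and 1 of 10. A list counted as found at an unadjusted p under 0.05 with camera, the list test described below. Genes vary together in the real libraries, so these rates of false calls and false lists need not hold for them.

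Comparisons, filters, tests, the rule for named genes and the patterns of 28 gene lists were set before the data were examined. The rule named, per comparison, up to 12 genes with the largest rise and 12 with the largest fall among called genes whose groups did not overlap, with 20 or more normalized counts in the higher group and an informative function text. It also took up to 4 members per list with the smallest p, and the 10 genes with the smallest p where fewer than 10 were called. For length, part of these genes are left out of the text. The list patterns were written for gene symbols and another wording of gene products. They were translated to the wording of the files after the function texts had been read and before any expression value was looked at, and the patterns as first written are kept as an alternative. Every one of the 1810 features carries a function text, of which 418 are uninformative, so 76.9% could match a list by meaning, and 579 features are in a list. The plan voided list results if fewer than 80% of the IDs matched a symbol or product. That bound is met if any function text counts and missed if uninformative texts do not, so list results are kept here with that limit. Lists therefore describe the annotated part of the genome.

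The 28 lists cover surface adhesins, sucrose use, glycogen and maltodextrin, lactose and galactose, PTS uptake, glycolysis, pyruvate fermentation, ATP synthase, ribosomal proteins, aminoacyl-tRNA synthetases, chaperones and Clp proteases, oxidative stress, competence, signal transduction, bacteriocins, arginine, purine and pyrimidine synthesis, branched-chain, aromatic and histidine amino acids, cysteine and methionine, fatty acids, cell wall, capsule, metals, ABC transport of peptides and amino acids, phage, cell division, and stable RNA as a sign of library make-up. Each list with 5 or more tested genes was tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation. It was also tested with fry, which asks whether the genes of a list move on balance one way. List p-values were adjusted by the Benjamini-Hochberg method over the lists of a comparison, and calls of single members were counted over all genes and when adjusted over the list alone.

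Alternatives set in advance were pseudocounts of 0.5, 5 and 10, no filter and a minimum mean of 50, library totals made equal, TMM factors, quantile normalization, limma without trend, robust variance moderation, array weights, a block for consecutive library numbers between the surfaces, a 2-fold minimum, an adjusted p under 0.01, and leaving out each replicate in turn. Others, chosen after seeing the data, were limma-voom on the recovered reads, one limma-voom fit of all 11 libraries, gene-by-gene array weights (statmod 1.5.0), fits on part of the biofilm libraries, and the block for lists. Replicate numbers only name the samples in the order of their records. For the overlap of both comparisons with planktonic cells, 100 pairs of unchanged groups were simulated from the residuals of whole libraries, each pair against 3 shared control libraries.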

Results

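Gene expression was measured by RNA-seq in Streptococcus oralis strain ATCC 9811, an oral streptococcus that lives in dental plaque. The 11 libraries formed 3 groups: 4 from biofilms on SLIPS, a slippery titanium surface whose structured face holds a film of liquid, 4 from biofilms on a titanium control surface, and 3 from planktonic cells, which grew suspended in the bioreactor. Reads in genes came to 10.9 to 14.4 M per SLIPS library, 11.8 to 17.5 M per titanium library and 11.01 to 11.68 M per planktonic library. Of the 1810 features listed, 8 to 13 were at 0 in a given library. Values are the authors' normalized counts, given as mean ± SD over the libraries of a group, and fold changes are on the scale of log2(normalized count + 1), which understates the change of low genes. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples.

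A few transcripts made up much of each library. The gene annotated as ClpE-like protein (peg.1480; contig 000001F, 686448 to 688553, minus strand) took 13.7 ± 1.11% of the reads in planktonic cells (SD, n = 3), 9.46 ± 1.90% on titanium (SD, n = 4) and 8.80 ± 2.32% on SLIPS (SD, n = 4). Glyceraldehyde-3-phosphate dehydrogenase (peg.446), an enzyme of glycolysis, took 7.62 ± 0.605%, 5.18 ± 0.518% and 5.66 ± 0.524% in the same order of groups. Together the 10 most abundant genes of a library took 44.7 ± 1.08% of the reads in planktonic cells, 34.3 ± 4.67% on titanium and 33.8 ± 4.43% on SLIPS.

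Each library was counted as one sample, and Pearson's r of log2 values between replicates of a group was 0.887 to 0.993 across genes. In the table that holds both surfaces, 79.8% of the variance lay on the first principal component. On it, replicates 1 and 3 of both surfaces scored from -23.3 to -17.0, and replicates 2 and 4 of both surfaces scored from 7.62 to 23.8. Values per library, which are not a test, are given for 2 gene lists. The median deviation of glycolysis genes from the group mean was 0.17 to 0.38 (log2) in replicates 1 and 3 of both surfaces and -0.56 to -0.14 in replicates 2 and 4. Genes for cysteine, methionine and sulfur uptake lay the other way, at -0.37 to -0.25 in replicates 1 and 3 and 0.10 to 0.49 in replicates 2 and 4.

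**Figure D1:**
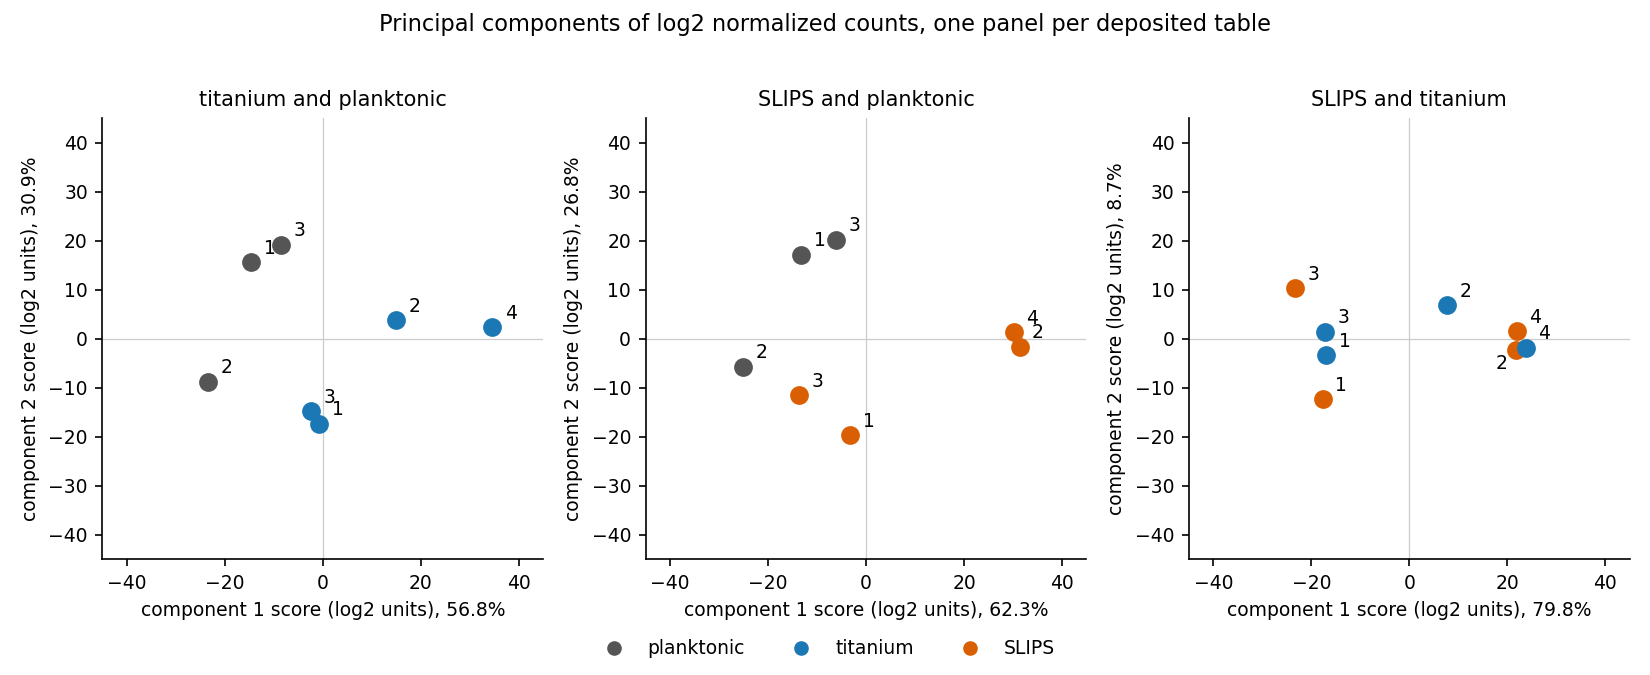
Scores of each library on the first principal component (horizontal axis) and the second (vertical axis), in log2 units, with one panel per deposited table, one point per library and numbers that name the replicates. In the panel of both surfaces, which holds 79.8% of the variance on component 1, titanium and SLIPS libraries lie on both sides of 0.

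Biofilm on titanium was compared with planktonic cells to describe how growth on the plain surface differed from growth in suspension. Biofilms came from the flow chambers and planktonic cells from the bioreactor. Surface, vessel and flow therefore cannot be told apart in either comparison with planktonic cells. On titanium, cells carried more transcript of a general stress protein and its neighbours. Relative to other genes, the lists of the ATP synthase that couples proton flow to ATP and of uptake systems for peptides and amino acids stood higher and that of purine synthesis lower with camera, and all 3 calls were lost with an estimated correlation (camera, BH adjusted p = 0.723 for each). The general stress protein of the Gls24 family (peg.1350; contig 000001F, 526156 to 526740, plus strand) stood at 28499 ± 11821 normalized counts on titanium (SD, n = 4) and 3229 ± 1900.2 in planktonic cells (SD, n = 3), a 9.13-fold rise with a log2 fold change of 3.19 (SE 0.44; limma, Benjamini-Hochberg (BH) adjusted p = 0.00879). L-lactate dehydrogenase (peg.995; contig 000001F, 159383 to 160369, plus strand), which makes lactate from pyruvate, was 2.40-fold lower, at 86637 ± 21279 against 204657 ± 33619 normalized counts, and fell by 1.26 on the log2 scale (SE 0.30; limma, BH adjusted p = 0.0431). In all, 134 of 1794 tested genes passed, of which 90 rose by 1.80-fold to 25.2-fold and 44 fell by 1.74-fold to 2.93-fold.

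Many of the larger rises lay in a pair of gene stretches. On contig 000001F, directly before Gls24, the small integral membrane protein (peg.1349; 525974 to 526144) rose 7.58-fold to 3135 ± 1038 normalized counts (limma, BH adjusted p = 0.00209). The hypothetical proteins peg.1347 (525064 to 525300) and peg.1348 (525400 to 525963), which lie just upstream and were picked out here after their values were seen, rose 25.2-fold and 17.3-fold (limma, BH adjusted p = 6.85e-05 and 5.91e-04). On contig 000002F, 6 adjacent genes of the minus strand, from 54135 to 58890, rose 4.31-fold to 5.56-fold. Among them, serine hydroxymethyltransferase (peg.1602), which moves one-carbon units from serine to folate, stood at 2948 ± 1163 against 623 ± 107 normalized counts (log2 fold change 2.18, SE 0.30; limma, BH adjusted p = 0.00879). Threonylcarbamoyl-AMP synthase (peg.1604), which acts in tRNA modification, stood at 2322 ± 760.5 against 402 ± 4.42 (log2 fold change 2.47, SE 0.27; limma, BH adjusted p = 0.00209). The other 4 were a release factor glutamine methyltransferase (peg.1605), a GNAT family acetyltransferase (peg.1603), a ribosomal RNA pseudouridylate synthase (peg.1601) and a homolog of pneumococcal vaccine antigen A (peg.1600). The tRNA adenosine-34 deaminase (peg.589) rose 5.43-fold, from 72.6 ± 5.35 to 409 ± 108 normalized counts (limma, BH adjusted p = 0.00308). Methylthioadenosine deaminase (peg.1065), a glutathione-dependent thiol reductase (peg.52) and tryptophan synthase alpha chain (peg.1356) rose 5.99-fold, 3.79-fold and 3.69-fold (limma, BH adjusted p = 0.0421, 0.0304 and 0.0405). Of these 12 genes with an informative name, 5 were still called without planktonic replicate 1, 8 without planktonic replicate 3 or titanium replicate 1, 7 without titanium replicate 2, 11 without planktonic replicate 2 or titanium replicate 4, and 12 without titanium replicate 3. Gls24 was not called without planktonic replicate 1 (limma, BH adjusted p = 0.0770).

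**Figure D2:**
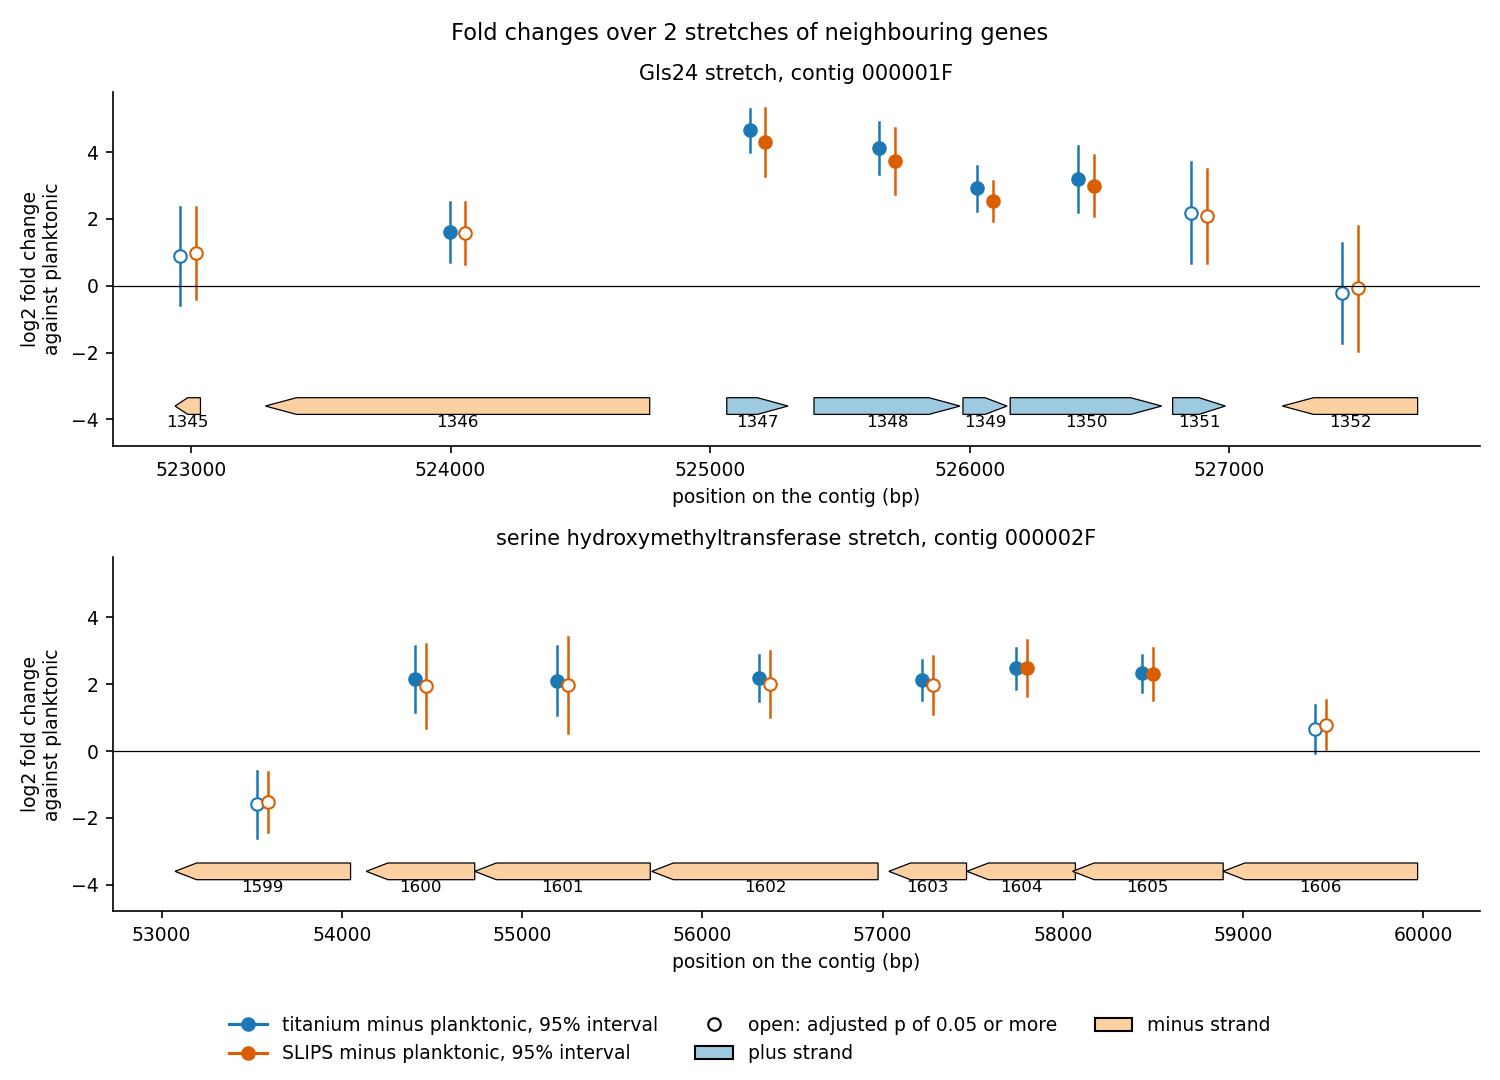
Log2 fold changes against planktonic cells (vertical axis, with 95% intervals) by position on the contig in base pairs (horizontal axis) for 2 stretches, with titanium (n = 4) in blue, SLIPS (n = 4) in orange, planktonic cells n = 3, filled points for adjusted p under 0.05 and arrows for the genes and their strand. Gls24 (peg.1350) had a log2 fold change of 3.19 on titanium and 2.99 on SLIPS, and threonylcarbamoyl-AMP synthase (peg.1604) 2.47 and 2.48.

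Among the falls, Xaa-Pro dipeptidase (peg.166; contig 000000F, 173814 to 174896, plus strand), a peptidase, went from 62611 ± 14146 normalized counts in planktonic cells to 22267 ± 5772 on titanium, 2.83-fold lower (limma, BH adjusted p = 0.0355). PdxU2 (peg.167), the substrate-specific part of a predicted vitamin transporter, and a tRNA pseudouridine synthase (peg.169) lie next to it or close by and were 2.60-fold and 2.63-fold lower (limma, BH adjusted p = 0.0355 and 0.0450). The toxin HigB (peg.240) and its antitoxin HigA (peg.239), a neighbouring pair, were 2.66-fold and 2.58-fold lower (limma, BH adjusted p = 0.0355 and 0.0421). S-ribosylhomocysteine lyase, LuxS (peg.1479; contig 000001F, 685805 to 686287, plus strand), which makes the precursor of the quorum signal autoinducer 2, was 2.23-fold lower, at 1259 ± 228 against 2798 ± 482 normalized counts (limma, BH adjusted p = 0.0355). The regulator of the multidrug efflux pump pmrA (peg.114) stood at 8468 ± 1941 against 20796 ± 1688 normalized counts, 2.51-fold lower (limma, BH adjusted p = 0.0355). Regulators of the Xre (peg.734), GntR (peg.549) and MarR (peg.803) families were 2.56-fold, 2.36-fold and 2.35-fold lower (limma, BH adjusted p = 0.0438, 0.0438 and 0.0438). With lactate dehydrogenase and a purine synthesis enzyme described with its list, these made 12 named falls. They were sensitive to the scaling and to single libraries. Over all tested genes the 44 called falls came to 5 with library totals made equal and to 0 with quantile normalization. Of the 12, 0 were called without planktonic replicate 1, planktonic replicate 3, titanium replicate 1 or titanium replicate 2, 8 without planktonic replicate 2 or titanium replicate 3, and 3 without titanium replicate 4.

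Of 28 gene lists tested on titanium, 3 were called with camera at its preset correlation. F-type ATP synthase genes stood high relative to other genes. Of 8 genes, 6 were called higher over all genes and 6 when adjusted over the list alone, with a median log2 fold change of 1.13 (camera, BH adjusted p = 3.17e-05, and adjusted p = 0.723 with an estimated correlation). Its c chain (peg.1670) went from 817 ± 41.7 to 2317 ± 437 normalized counts, 2.80-fold (limma, BH adjusted p = 0.0125), and the b (peg.1668), delta (peg.1667) and a (peg.1669) chains rose 2.35-fold, 2.31-fold and 2.19-fold (limma, BH adjusted p = 0.0338, 0.0338 and 0.0355). Peptide and amino acid ABC transporters also stood high, with 8 of 39 genes called higher and 0 lower, 17 higher and 1 lower when adjusted over the list alone, and a median of 0.82 (camera, BH adjusted p = 3.17e-05, and adjusted p = 0.723 with an estimated correlation). Examples were the ATP-binding protein of a methionine transporter (peg.717), 3.14-fold higher, and LivG (peg.101) and LivH (peg.103) of a branched-chain amino acid transporter, 3.51-fold and 3.28-fold higher (limma, BH adjusted p = 0.0325, 0.0338 and 0.0338), with LivK (peg.104), which binds leucine for it, 2.11-fold higher (limma, BH adjusted p = 0.0355). Purine synthesis genes stood low relative to other genes, with 0 of 16 called higher and 3 lower, 1 higher and 10 lower when adjusted over the list alone, and a median of -0.68 (camera, BH adjusted p = 0.0155, and adjusted p = 0.723 with an estimated correlation). Against no change, fry did not call the purine list (BH adjusted p = 0.0644), and under equal totals its median was -0.04. The called members were N5-carboxyaminoimidazole ribonucleotide synthase (peg.557) and, beside it, phosphoribosylamine-glycine ligase (peg.559) and N5-carboxyaminoimidazole ribonucleotide mutase (peg.558), 2.29-fold, 2.07-fold and 2.03-fold lower (limma, BH adjusted p = 0.0421, 0.0421 and 0.0450). These 3 lists kept their camera calls whichever library was left out. Of the 11 called members named here, 0 were called without planktonic replicate 1, 2 without planktonic replicate 3 or titanium replicate 1, 1 without titanium replicate 2, 8 without titanium replicate 3, 6 without titanium replicate 4 and 11 without planktonic replicate 2. With the list patterns in their first wording, before they were matched to the function texts of the files, 1 list was called. The ATP synthase list then held 3 genes, under the 5 needed, so it was not tested.

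The other 25 lists were not called by camera on titanium, though single members passed. In pyruvate fermentation (2 of 14 genes higher, 1 lower; 5 and 2 adjusted over the list alone) the E2 component of pyruvate dehydrogenase (peg.880) and a formate transporter (peg.992) rose 2.58-fold and 2.60-fold (limma, BH adjusted p = 0.0355 and 0.0421). In sucrose use (0 of 11 higher, 2 lower; 0 and 5 adjusted over the list alone) sucrose-6-phosphate hydrolase (peg.254) and the sucrose operon repressor ScrR (peg.255) were 1.92-fold and 1.87-fold lower (limma, BH adjusted p = 0.0421 and 0.0438). Ribosomal protein genes split, with 4 of 53 higher and 2 lower (4 and 3 adjusted over the list alone). As a list against no change, fry called them lower (BH adjusted p = 0.0346), with 34 of 53 genes below 0 and a median of -0.34, while camera did not (BH adjusted p = 0.144). Equal totals moved fold changes up by a median of 0.64 (log2), more than this list lay below 0. The direction against no change therefore depends on the scaling. S13 (peg.792) rose 2.07-fold and S2 (peg.630) was 1.97-fold lower (limma, BH adjusted p = 0.0338 and 0.0421). Aminoacyl-tRNA synthetases split as well (1 of 21 higher, 3 lower, and as many when adjusted over the list alone), with the enzyme for cysteine (peg.231) 2.53-fold higher and that for alanine (peg.1091) 2.07-fold lower (limma, BH adjusted p = 0.0405 and 0.0355). In cell wall synthesis (3 of 35 higher, 0 lower, and as many when adjusted over the list alone) the rod shape proteins MreD (peg.628) and MreC (peg.627) rose 3.65-fold and 2.74-fold (limma, BH adjusted p = 0.0355 and 0.0450). In division and replication (3 of 49 higher, 0 lower, and as many when adjusted over the list alone) NrdI (peg.724) and NrdH (peg.1622), partners of a ribonucleotide reductase, rose 2.99-fold and 3.16-fold (limma, BH adjusted p = 0.0405 and 0.0421). The competence protein CoiA (peg.1712) was 2.09-fold lower in a list with 0 of 28 genes higher and 2 lower, and as many when adjusted over the list alone (limma, BH adjusted p = 0.0405). Glycolysis had 0 of 11 genes called over all genes, and 0 higher and 4 lower when adjusted over the list alone, with a median of -0.52 (camera, BH adjusted p = 0.0576). The move under equal totals (0.64) is larger than this median as well. Without planktonic replicate 1 or titanium replicate 2, 0 of the 26 called members of these lists that the naming rule took were called. The number was 1 without planktonic replicate 3 or titanium replicate 1, 5 without titanium replicate 4, 12 without titanium replicate 3 and 21 without planktonic replicate 2.

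These counts came from limma on log2 values with BH adjustment over all tested genes. The 134 called genes all had every library of one group above every library of the other. Non-overlapping groups were seen in 529 of the 1794 tested genes (29.5%), where chance alone gives 5.71% as a mean over splits. Genes vary together, so the share in any single split can lie far from that mean. An unadjusted limma p under 0.05 was seen for 548 genes. Leaving out 1 library gave 7 called genes without planktonic replicate 1, 15 without planktonic replicate 3, 18 without titanium replicate 1, 10 without titanium replicate 2, 83 without titanium replicate 3, 41 without titanium replicate 4 and 201 without planktonic replicate 2. Scaling every library to the same total moved the median of all genes up by 0.64 (log2) and gave 440 rises and 5 falls, and quantile normalization gave 20 rises and 0 falls. With array weights limma called 533 genes (296 higher, 237 lower), and the fit of these weights stopped before convergence. Under equal totals the median of the purine synthesis list was 0.64 below that of all genes, as it was with the authors' scaling. Equal totals move the fold changes of all genes nearly alike, so this match was fixed in advance and is no check of the list.

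SLIPS biofilm was compared with planktonic cells in the same way. The 7 called genes all rose, and 6 of them lay in the stretches described on titanium. Gls24 (peg.1350) stood at 22879 ± 7945 normalized counts on SLIPS (SD, n = 4) and 3067 ± 1792 in planktonic cells (SD, n = 3), 7.94-fold higher with a log2 fold change of 2.99 (SE 0.40; limma, BH adjusted p = 0.0162). Its neighbours, the small integral membrane protein (peg.1349) and the hypothetical proteins peg.1347 and peg.1348, rose 5.83-fold, 19.8-fold and 13.4-fold (limma, BH adjusted p = 0.00546, 0.00546 and 0.00607). Threonylcarbamoyl-AMP synthase (peg.1604) and the release factor glutamine methyltransferase (peg.1605) beside it rose 5.58-fold and 4.94-fold (limma, BH adjusted p = 0.0229 and 0.0229), and the tRNA adenosine-34 deaminase (peg.589) rose 5.23-fold, from 69.0 ± 4.95 to 369.7 ± 73.5 normalized counts (limma, BH adjusted p = 0.00597). Of these 7, 0 were called without planktonic replicate 1, 4 without SLIPS replicate 1 or planktonic replicate 3, 5 without SLIPS replicate 4 or planktonic replicate 2, and 7 without SLIPS replicate 2 or SLIPS replicate 3. Quantile normalization kept 5 of the 7 calls and lost those of peg.1604 and peg.1605.

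With camera at its preset correlation, 6 of 28 lists were called on SLIPS against planktonic cells, and with an estimated correlation 0 were (adjusted p = 0.726 for each of the 6). No member of the 6 lists was called over all genes, so their members are given as values. ABC transporters of peptides and amino acids had a median log2 fold change of 0.90, with 17 of 39 genes higher and 0 lower when adjusted over the list alone (camera, BH adjusted p = 1.93e-05). LivG (peg.101) and LivH (peg.103) were at 3.98 and 3.74 times the planktonic level (limma, BH adjusted p = 0.0894 for both). F-type ATP synthase had a median of 0.98, with 5 of 8 higher and 0 lower when adjusted over the list alone (camera, BH adjusted p = 8.26e-04). Lactose and galactose metabolism had a median of -0.72, with 0 of 20 higher and 5 lower when adjusted over the list alone (camera, BH adjusted p = 0.00391). A tagatose-bisphosphate aldolase (peg.1630) had a log2 fold change of -1.18 (SE 0.28; limma, BH adjusted p = 0.0894). Purine synthesis had a median of -0.70, with 0 of 16 higher and 3 lower when adjusted over the list alone (camera, BH adjusted p = 0.0180). Surface adhesins had a median of -0.54, with 0 of 28 called either way (camera, BH adjusted p = 0.0360). The hemagglutinin/hemolysin-related proteins peg.1129 and peg.216 had log2 fold changes of -1.09 and -1.04 (limma, BH adjusted p = 0.103 and 0.106). The list of cysteine, methionine and sulfur uptake had a median of 0.76, with 1 of 17 higher and 0 lower when adjusted over the list alone (camera, BH adjusted p = 0.0360). The adhesin call was lost without SLIPS replicate 2, planktonic replicate 1 or planktonic replicate 3 (camera, BH adjusted p = 0.0541, 0.0640 and 0.0786), and the cysteine and methionine call without SLIPS replicate 2, SLIPS replicate 4 or planktonic replicate 2 (camera, BH adjusted p = 0.0541, 0.0619 and 0.0798). Quantile normalization also lost both calls (camera, BH adjusted p = 0.256 for adhesins and 0.0765 for cysteine and methionine), and equal totals lost the latter (camera, BH adjusted p = 0.0543). With the list patterns in their first wording, 2 lists were called, and ATP synthase was again not tested. Scaled to equal totals, the adhesin, lactose and purine lists stood at medians of 0.12, -0.06 and -0.04, against a median of 0.61 for all genes. Against no change, fry called 0 of the 6 lists (BH adjusted p = 0.106 to 0.216).

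In this comparison limma tested 1792 genes with BH adjustment and called 7, while 487 had an unadjusted p under 0.05 and 458 (25.6%) had non-overlapping groups. The count was 0 without planktonic replicate 1, 4 without planktonic replicate 3 or SLIPS replicate 1, and 224 without SLIPS replicate 3. With equal totals, which moved the median of all genes up by 0.66 (log2), limma called 303 genes, all of them higher. With array weights limma called 1049 genes (508 higher, 541 lower), though the fit of these weights stopped before convergence.

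The fold changes of both biofilms against planktonic cells ran closely together across genes. The 7 genes called on SLIPS, Gls24 among them, were all called on titanium too, and all 134 genes called on titanium had a fold change of the same sign on SLIPS. If both sets of calls were independent, 0.35 genes would be expected to rise in both. Across the 1792 genes tested in both, which are not independent replicates, Pearson's r of the log2 fold changes was 0.982 and the covariance was 0.544. Both comparisons used the same 3 planktonic libraries, and 100 simulated pairs of unchanged groups against those controls gave a mean r of 0.42 (95% of sets from -0.735 to 0.980) and a mean covariance of 0.069 (95% of sets from -0.101 to 0.396). In 1 of the 100 sets genes were called in both, 309 of them, so an overlap of 7 without any change is not excluded. Whole libraries were drawn with replacement, and a set that repeats a library can have too little spread. That count is therefore not shown to come from the shared controls. The covariance exceeded the simulated mean by 0.475, and 1 of the 100 simulated sets reached it. Since 3 controls cannot be split into groups of 2, part of the excess may come from the shared controls. The simulation also drew the libraries of both surfaces independently. Their deviations from the group mean correlated at r 0.565 to 0.906 for the same replicate number, so the simulated covariance may be too low. The count in both was 0 without planktonic replicate 1, 4 without planktonic replicate 3 or SLIPS replicate 1, and 104 without SLIPS replicate 3.

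**Figure D3:**
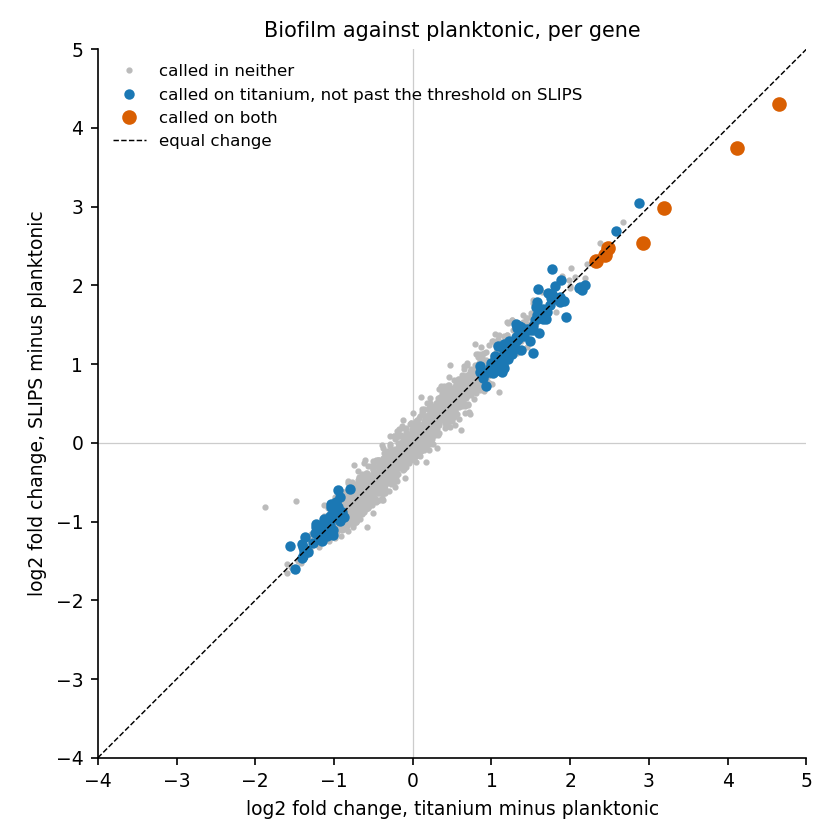
Log2 fold change on SLIPS against planktonic cells (vertical axis) by that on titanium against planktonic cells (horizontal axis), one point per gene tested in both (1792), coloured by where the gene was called. Points lie along the diagonal (Pearson's r 0.982 across genes), and the 7 genes called in both lie at the upper right.

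SLIPS was then compared with titanium directly, which addresses how biofilm cells on the repellent surface differed from those on the plain one. With limma without library weights, no single gene differed past the threshold between the surfaces. Gls24 (peg.1350), at 30525 ± 11080.4 normalized counts on SLIPS and 36163 ± 15571 on titanium (SD, n = 4 each), had a log2 fold change of -0.20 (SE 0.37; limma, BH adjusted p = 1.000). The gene with the smallest p was a cadmium resistance protein (peg.1259; contig 000001F, 429241 to 429852, minus strand), at 2094 ± 336 on SLIPS and 1640.0 ± 192 on titanium, with a log2 fold change of 0.35 (95% interval -0.08 to 0.78; limma, BH adjusted p = 1.000). Alpha-acetolactate decarboxylase (peg.1104), the toxin MazF (peg.852) and ribosomal protein L18 (peg.784) were examples of the other genes that the rule took by smallest p. Their log2 fold changes were 0.47, 0.40 and -0.26 (limma, BH adjusted p = 1.00 for each).

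Of 1794 genes tested, limma called 0 after BH adjustment and 0 had an unadjusted p under 0.05, and limma-voom on reads recovered from the values also called 0. With array weights, set in advance, limma called 456 genes (241 higher, 215 lower). That fit gave SLIPS replicates 2 and 4 weights of 3.67 and 4.94 and replicates 1 and 3 weights of 0.264 and 0.240, so it rested mainly on 2 of the 4 SLIPS libraries. The 24 genes named by the rule in the comparisons with planktonic cells had log2 fold changes of -0.38 to 0.21 between the surfaces, with a median of -0.04. A difference of 2-fold or more lay outside the 95% interval for 1225 genes (68.3%), so for the remaining 569 genes, a change of that size was not excluded in this fit. The spread along the first principal component, which both surfaces share, widens these intervals: chance alone gives 89.7 genes with an unadjusted p under 0.05. With a block for consecutive library numbers, which the labels do not state to be shared, the interval excluded 2-fold for 1782 genes (99.3%), and limma called 0 genes after BH adjustment, with 9 at an unadjusted p under 0.05. Non-overlapping groups were seen in 3 genes (0.167%), where chance gives 2.86% as a mean over splits.

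Some gene lists lay slightly to one side between the surfaces. With camera at its preset correlation, 5 of 28 lists were called, and 0 with an estimated correlation. Glycogen and maltodextrin metabolism had a median log2 fold change of -0.19, with 17 of 19 genes below 0 (camera, BH adjusted p = 7.31e-06, and adjusted p = 0.836 with an estimated correlation). Its glycogen synthase (peg.900) stood at 5029 ± 409 normalized counts on SLIPS and 5766 ± 627 on titanium (log2 fold change -0.19, SE 0.16; limma, BH adjusted p = 1.000), and maltodextrin phosphorylase (peg.493) had a log2 fold change of -0.19. Lactose and galactose metabolism had a median of -0.13, with 18 of 20 below 0 (camera, BH adjusted p = 0.00875, and adjusted p = 0.924 with an estimated correlation). Surface adhesins had a median of -0.09, with 21 of 28 below 0 (camera, BH adjusted p = 0.0235, and adjusted p = 0.836 with an estimated correlation). Competence and DNA uptake had a median of 0.06, with 22 of 28 above 0 (camera, BH adjusted p = 0.0187, and adjusted p = 0.836 with an estimated correlation). Peptide and amino acid ABC transport had a median of 0.10, with 30 of 39 above 0 (camera, BH adjusted p = 0.0361, and adjusted p = 0.836 with an estimated correlation). In all 5 lists, 0 genes were called over all genes and 0 when adjusted over the list alone. Per library, without a test, lactose and galactose genes had median deviations of 0.18 to 0.58 in replicates 1 and 3 of both surfaces and -0.48 to -0.23 in replicates 2 and 4. The glycogen call was lost without titanium replicate 1 (camera, BH adjusted p = 0.750), and without that library the lactose list turned to the other direction (camera, BH adjusted p = 0.750). Equal totals and quantile normalization lost the call of peptide and amino acid transport (camera, BH adjusted p = 0.145 and 0.0532). The number of lists called was 8 without SLIPS replicate 1, 2 without SLIPS replicate 2, SLIPS replicate 4 or titanium replicate 1, 1 without titanium replicate 3 and 9 without titanium replicate 4.

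**Figure D4:**
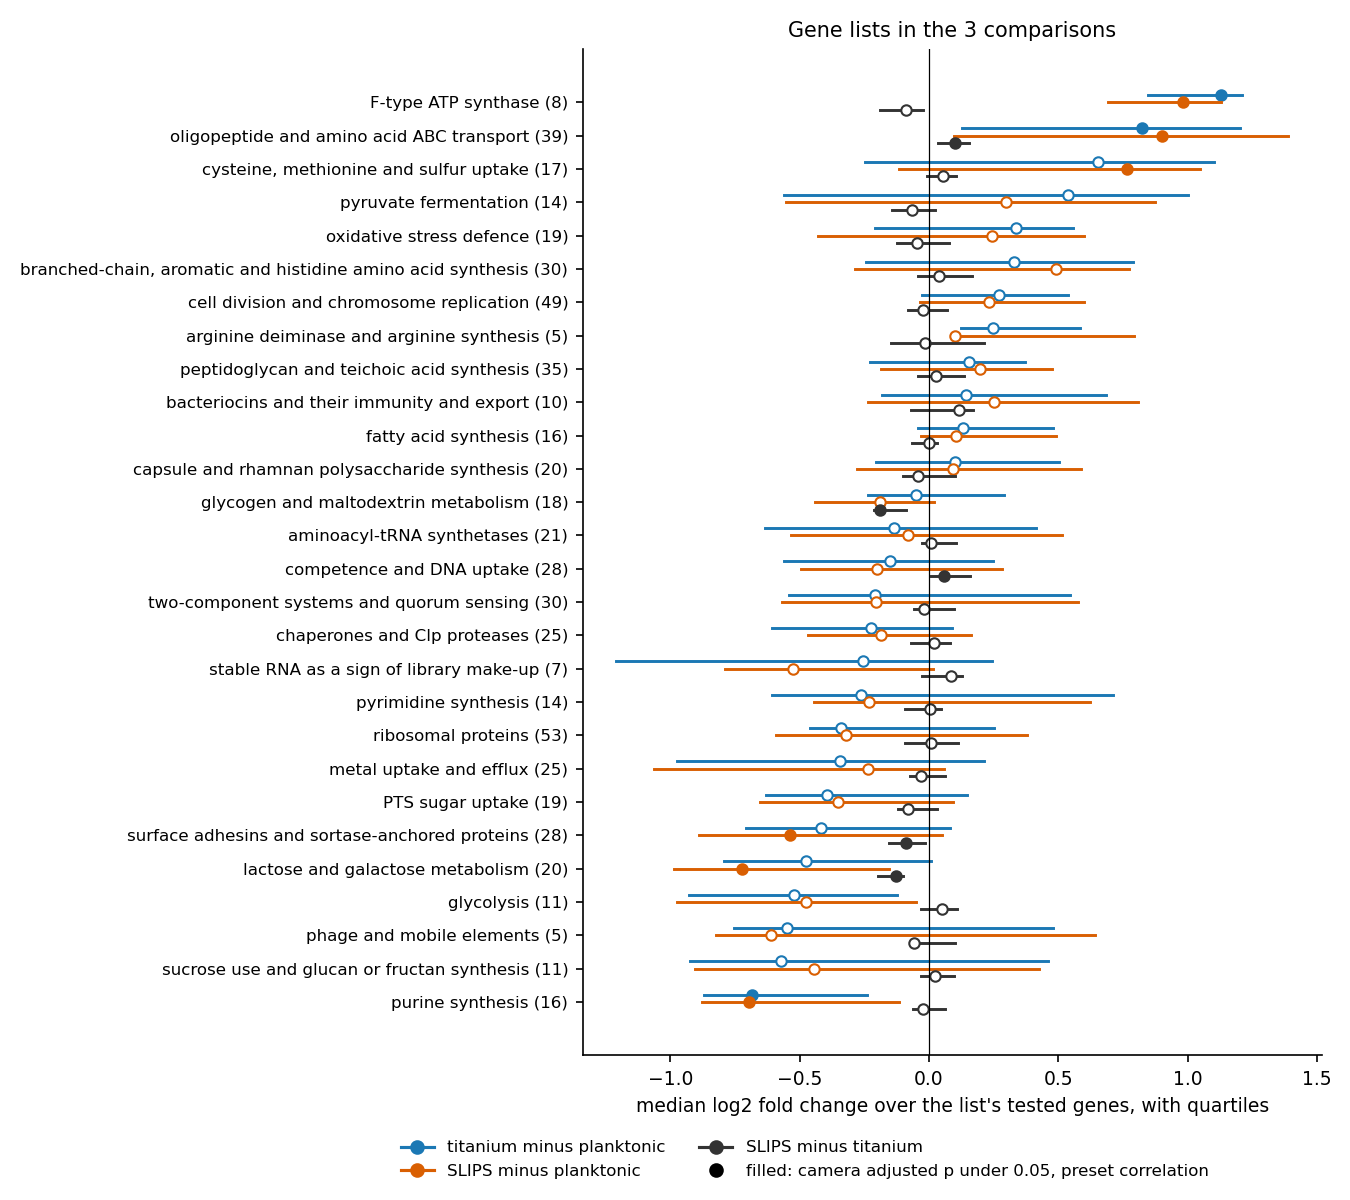
Median log2 fold change over the tested genes of each of 28 gene lists (horizontal axis, in log2 units, with bars for the quartiles), one line per list with its number of genes, in the 3 comparisons, with filled points where camera at its preset correlation gave an adjusted p under 0.05. F-type ATP synthase lies at 1.13 on titanium and 0.98 on SLIPS against planktonic cells and at -0.09 between the surfaces.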

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

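The tests of library numbers, of scaling, of background, of coding length, and of the slope of fold changes were chosen after the result was seen; the other tests here were set beforehand. Among the values of named genes and 3 measures of the libraries, 142 groups of 4 libraries were searched for a library that lay far from the other 3. The search found 9 (6.34%), where chance gives about 5%. In titanium against planktonic cells, PdxU2 (peg.167) stood at 1051 normalized counts in titanium replicate 2 and at 614 to 666 in the others. The antitoxin HigA (peg.239) stood at 3281 in titanium replicate 3 and at 1871 to 2012 in the others. The cadmium resistance protein (peg.1259) stood at 1063 in titanium replicate 1 and at 1354 to 1413 in the others. Glyceraldehyde-3-phosphate dehydrogenase (peg.446) stood at 384585 in titanium replicate 4 and at 612964 to 642112 in the others; without that library limma called its fall (BH adjusted p = 0.0389, against 0.0580 with all libraries). The small integral membrane protein beside Gls24 (peg.1349), in SLIPS against planktonic cells, stood at 3150 in SLIPS replicate 2 and at 1857 to 2070 in the others.

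Between the surfaces, a thiol:disulfide oxidoreductase (peg.1157) stood at 526.0 normalized counts in SLIPS replicate 3 and at 399 to 418 in the others. DNA-3-methyladenine glycosylase (peg.736) stood at 1114 in titanium replicate 4 and at 800.7 to 840.5 in the others. Maltodextrin phosphorylase (peg.493) stood at 5354 in titanium replicate 1 and at 3554 to 3709 in the others. A substrate-binding protein of an ABC transporter for basic amino acids or glutamine (peg.1106) stood at 2429 in SLIPS replicate 1 and at 967 to 1096 in the others.

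The 8 biofilm libraries fell into 2 sets along the first principal component, with replicates 1 and 3 on one side and 2 and 4 on the other, whatever the surface; the labels name no batch, and no biological explanation was tested, since no group of the design follows this split. The authors' scaling is argued against, since the component kept at least 79.7% of the variance, and the sets stayed apart, under 3 other scalings. Without the 10 most abundant genes it held 79.8%. That cannot decide on such genes, since so few weigh little on the log2 scale. A uniform background of DNA or a coding length bias as the whole cause is argued against too: the sets stayed apart among the 449 genes most abundant per base (25%), where the component held 79.85% of the variance, and within each of 4 classes by coding length (74.4% or more). As part of the cause a background stays open, since its bound from the 5th percentile of genes was 2.21 to 3.47% of reads in replicates 2 and 4 and 1.47 to 1.87% in 1 and 3, and the loadings fell with abundance per base (Spearman's rho -0.253 across genes). A batch marked by consecutive library numbers stays open: 6 of 8 libraries correlated best with the same number on the other surface (r 0.781 to 0.906 across genes), but replicate 2 of both surfaces did not (r 0.565), and SLIPS replicate 2 correlated with titanium replicate 4 at 0.886. On the first component beside SLIPS (62.3% of the variance), SLIPS replicates 2 and 4 scored 31.3 and 30.1. SLIPS replicates 1 and 3 (-3.23 and -13.7) lay near or among the planktonic libraries (-25.1 to -6.22). Beside titanium (56.8%), replicates 2 and 4 scored 15.0 and 34.6, replicates 1 and 3 -0.717 and -2.43, and planktonic libraries -23.4 to -8.49. The split thus also runs along the main component of both comparisons with planktonic cells. The planktonic libraries may share this split, which was not tested. On the second component beside titanium, planktonic replicate 2 (-8.81) and titanium replicates 1 and 3 (-17.4 and -14.8) lay below 0. Planktonic replicates 1 and 3 (15.7 and 19.2) and titanium replicates 2 and 4 (3.75 and 2.36) lay above it. Beside SLIPS the sides were the same except for SLIPS replicate 2 (-1.63). Both comparisons with planktonic cells were fitted without a block.

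On titanium 134 genes were called against planktonic cells and on SLIPS 7, while the fold changes ran together. At an unadjusted limma p under 0.05 the counts were 548 and 487. With 1 library left out, called genes came to 7 to 201 on titanium and 0 to 224 on SLIPS. The gap thus depends on the threshold and on single libraries. Changes on SLIPS smaller by 20% or more were not seen, but they stay open. Over the 134 genes the difference between the surfaces was set against the change on titanium, which shares the titanium libraries. The slope was -0.031 (-0.123 to 0.081 with 1 biofilm library left out), where such a shrinkage gives -0.2. That range does not measure the spread between libraries. In 23 of 100 simulated pairs of unchanged groups, the slope of SLIPS on titanium changes over as many genes was 0.9 or more (0.97 here). A smaller shrinkage stays open too. A wider spread among the SLIPS libraries may account for the gap: the median ratio of the SDs, SLIPS over titanium, was 1.18, and 71.9% of genes had the wider spread on SLIPS. That ratio lay between the bounds set for and against this explanation (1.2 and 1), which keeps it open.

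Genes called on titanium lay next to each other on the contigs, in 10 runs of 3 or more genes that held 45 of them, such as the 6 ATP synthase genes and the 6 genes around serine hydroxymethyltransferase. A chance order is argued against: 77 of the 134 called genes had a called neighbour, against a mean of 19.1 and a highest value of 42 in 10000 random draws of as many genes. The draws took genes as independent of their neighbours, so they do not bear on whether the calls reflect the groups. A change over whole stretches whatever the strand stays open, since 92.2% of the neighbouring called pairs (47 of 51) shared a strand, against 84.4% of all neighbouring pairs, and the upper bound of random draws was 94.1%. Transcription of these runs as operons may be a further account, as a hypothesis that the tables do not test apart from it.

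Other splits of the same libraries into groups of the same sizes were tried for every count. For genes called on titanium against planktonic cells, 2 of 35 splits gave as many (134 for the real split, 146 for the highest other), so chance could not be excluded. The split with 146 set planktonic replicates 1 and 3 with titanium replicates 2 and 4 against the rest, along the 2 sets of biofilm libraries. The like split with SLIPS replicates 2 and 4 gave 170 genes. For genes called on SLIPS against planktonic cells, 4 of 35 splits gave as many (7 for the real split, 298 for the highest other, SLIPS replicate 3 with the planktonic libraries), and chance could not be excluded; that high count points to a structure among the libraries. Between the surfaces the real split gave 0 genes, which every one of the 35 splits reaches, so the count of splits says nothing there. The highest other, 1171 genes for replicates 1 and 3 of both surfaces against 2 and 4, points to the same structure. For the lists, chance could not be excluded in any comparison: 25 of 35 splits gave as many on titanium (3 for the real split, 12 for the highest other), 9 of 35 on SLIPS (6 and 12) and 18 of 35 between the surfaces (5 and 9).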

How the results depend on the processing

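The fits with voom, gene-by-gene array weights, part of the biofilm libraries, the block for lists and the first wording of lists were chosen after seeing the data. No gene call with all libraries turned direction in any setting. The groups of every called gene did not overlap, so leaving libraries out could not have turned one. The 134 genes on titanium came to 445 with equal totals (440 higher, 5 lower; 94 of the 134 among them), 20 with quantile normalization, 533 with array weights (296 higher, 237 lower), 582 with gene-by-gene array weights, 9 at an adjusted p under 0.01, and 7 to 201 with 1 library left out. With titanium replicates 1 and 3 only they came to 52, and with 2 and 4 only to 365; these pairs were picked from the first principal component, are not groups of the study, and are no evidence about any. The settings not named here gave 94 to 137, limma-voom on recovered reads 107, all among the 134. The 7 genes on SLIPS came to 303 with equal totals, 1049 with array weights (508 higher, 541 lower), 1102 with gene-by-gene array weights, 51 in the voom fit of all 11 libraries, 774 with SLIPS replicates 2 and 4 only (7 with 1 and 3 only), 4 at an adjusted p under 0.01, and 0 to 224 with 1 library left out; limma-voom gave 7. The 0 genes between the surfaces came to 456 with array weights (241 higher, 215 lower), which gave SLIPS replicates 2 and 4 weights of 3.67 and 4.94 and the other 2 weights of 0.264 and 0.240; gene-by-gene array weights gave 0 (265 at an unadjusted p under 0.05), and all other settings gave 0. The array weight fit stopped before convergence in both comparisons with planktonic cells. Genes called in both biofilms came to 295 with equal totals, 46 in the voom fit of all 11 libraries, 4 at an adjusted p under 0.01, and 0 to 104 with 1 library left out.

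Of the 28 lists, the 3 called on titanium came to 5 with a minimum mean of 50, 5 with equal totals, 7 with quantile normalization, 6 without trend, 1 with the first wording, 0 with an estimated correlation, 4 with fry (purine lost, ribosomal proteins and arginine gained), and 3 to 8 with 1 library left out. Only the authors' scaling was used for fry. Equal totals moved fold changes up by a median of 0.64 (log2), more than the ribosomal median of -0.34 lay below 0. The 6 on SLIPS came to 0 with an estimated correlation, 0 with fry and 2 with the first wording. The 5 between the surfaces came to 0 with an estimated correlation, 0 with fry, and 1 to 9 with 1 library left out; the adjusted p of the lactose and galactose list then ran from 4.41e-05 to 0.750, the latter without titanium replicate 1 and in the other direction. Among 66 named genes called on titanium, 51 lost the call with quantile normalization, 21 with equal totals, 21 in the voom fit of all 11 libraries and 9 with limma-voom on recovered reads. Of the 462 calls of these genes with 1 library left out, 295 were lost. The cause of these shifts was not tested.

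The labels give no shared replicate numbers. With consecutive library numbers as a replicate block, set in advance for genes, 0 genes (9 at an unadjusted p under 0.05) and 5 lists were called between the surfaces. The block changed no call, and not every library correlated best with its own number, which is a hint from the data, not the design. The planned edgeR and DESeq2 fits on recovered reads were not run, because too few low values stood in each column to meet the check set for such reads. The spread between replicates, not depth, limits these results.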

Other observations

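The values per library and the 3 genes at the end of this part were chosen after the results were seen, and the lists were set beforehand. Several further gene groups differed along the first principal component of the biofilm libraries. Genes for branched-chain, aromatic and histidine amino acid synthesis had median deviations from the group mean of -0.35 to -0.28 (log2) in replicates 1 and 3 of both surfaces and 0.20 to 0.35 in replicates 2 and 4. Metal uptake and efflux genes lay the same way, at -0.37 to -0.10 and 0.22 to 0.36. PTS sugar uptake genes lay the other way, at 0.12 to 0.51 and -0.39 to -0.25. Fatty acid synthesis genes stood at -0.54 in titanium replicate 1 and -0.50 in SLIPS replicate 1, against -0.06 and -0.03 in replicate 3 of each surface and 0.13 to 0.42 in replicates 2 and 4. These are values per library and not a test.

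The remaining lists were not called on titanium against planktonic cells, and most were not called on SLIPS either. Lactose and galactose metabolism had a median log2 fold change of -0.48 on titanium with 1 of 20 genes lower, a tagatose-bisphosphate aldolase (peg.1630, 2.13-fold lower; limma, BH adjusted p = 0.0438), and 0 when adjusted over the list alone (camera, BH adjusted p = 0.0550). Cysteine, methionine and sulfur uptake had a median of 0.65, with 2 of 17 higher and 9 when adjusted over the list alone (camera, BH adjusted p = 0.0520). Surface adhesins had a median of -0.42 with 1 of 28 higher (camera, BH adjusted p = 0.111). PTS uptake, chaperones and Clp proteases, bacteriocins, arginine metabolism, capsule, glycogen and maltodextrin, phage and stable RNA had 0 called genes over all genes, with medians of -0.40, -0.22, 0.14, 0.25, 0.10, -0.05, -0.55 and -0.26 (camera, BH adjusted p = 0.275, 0.269, 0.511, 0.269, 0.511, 0.808, 0.511 and 0.483). Against no change, fry called the arginine list higher on titanium (BH adjusted p = 0.0346), with 4 of 5 genes above 0. Adjusted over the list alone, 1 bacteriocin gene and 1 arginine gene were called higher. Oxidative stress defence had 2 of 19 genes higher, glutathione reductase (peg.1039, 2.02-fold) among them, with a median of 0.34 (limma, BH adjusted p = 0.0438; camera, BH adjusted p = 0.275). Signal transduction had 2 of 30 higher and 1 lower, LuxS, with a median of -0.21 (camera, BH adjusted p = 0.511). Pyrimidine synthesis had 2 of 14 higher, with CTP synthase (peg.1402) 2.24-fold higher (limma, BH adjusted p = 0.0377), a median of -0.26 and a mean of 0.02, which differ in sign (camera, BH adjusted p = 0.787). Branched-chain, aromatic and histidine amino acid synthesis had 1 of 30 higher with a median of 0.33, fatty acid synthesis 1 of 16 higher with 0.13, and metal uptake 1 of 25 lower with -0.34 (camera, BH adjusted p = 0.269 for each of the 3). The glycogen list also differed in sign between its median and its mean of 0.03. Ribosomal proteins, aminoacyl-tRNA synthetases, sucrose use, pyruvate fermentation, cell wall, division and competence had camera BH adjusted p of 0.144, 0.511, 0.269, 0.269, 0.375, 0.0865 and 0.269.

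The ClpE-like gene (peg.1480), picked out here because it had the most reads, lies beside LuxS (peg.1479) on the opposite strand. It stood at a log2 fold change of -1.20 on titanium against planktonic cells (95% interval -2.10 to -0.29; limma, BH adjusted p = 0.0851) and of -1.33 on SLIPS (limma, BH adjusted p = 0.102). In front of Gls24, the Mga regulator gene (peg.1346) on the minus strand rose 3.05-fold on titanium (limma, BH adjusted p = 0.0438), and the hypothetical protein that follows Gls24 (peg.1351) had a log2 fold change of 2.19 (limma, BH adjusted p = 0.0713); both were looked at after their values were seen.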
